A study of Mus musculus with 6 samples.

How the data were processed

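The values analysed were gene-level FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments) as deposited by the authors, 1 table per library. RNA was extracted as total RNA, amplified with a full-length cDNA kit and made into libraries by tagmentation, a route that does not keep the strand. Per the submitters' processing notes, reads were aligned to the mm10 genome with TopHat2 2.1.1 and Bowtie2 2.2.8, handled with SAMtools 0.1.18 and quantified with Cuffdiff 2.2.1. The annotation release, program options and read numbers were not given in the sources used here. Without strand, reads from antisense or overlapping genes may count toward a gene, and reads of close paralogs may be divided between them. A gene-level value also sums all exons, so it need not show the loss of 1.

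The groups, gene lists, filter, tests, named-gene rule and most alternatives were chosen before the data were examined. Analysis used R 4.3.3 and limma 3.58.1 on log2(FPKM + 1). Of 24346 genes, 11429 had an FPKM of at least 1 in at least 3 libraries and were tested with moderated t statistics with a variance trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p values for genes are from limma, and those for lists are from limma's camera. Unless stated otherwise, camera used a preset correlation between genes of 0.01, and it was repeated with a correlation estimated for each list. Of 25 pathway lists and 16 cell type lists fixed in advance, those with at least 5 tested genes were tested, which were 23 and 8. The 2 pathway lists left out were interferon ligands and receptors and mitochondrial-encoded transcripts. Adjustment over the list alone means adjustment across the tested members of 1 list. Il10ra, below the filter, was compared with an exact permutation test, as were per-library list means. Values after ± are SD across 3 libraries, or SE where marked.

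Named genes were the targeted gene, its partner and the sort genes, 5 genes per direction with the lowest unadjusted p, 3 members of each list that passed (5 for type I interferon), and the most abundant member of each other list. Of the genes this rule names, 3 are not reported here. Locations were taken from GENCODE M21, in which 23932 of the 24346 names matched a gene. The procedure was tested on simulated data in which genes varied independently of each other. The changed genes were drawn only from those with a mean above about 5 FPKM, and both groups were given the same spread. Of genes changed by a log2 of 1, 64.8% were recovered, and of genes changed by a log2 of 2, 96.4%, with 7.6 false calls on average. These rates hold for such genes only, so a count of 0 in the data does not rule out changes of these sizes. A list shifted by 0.75 was called in 5 of 5 runs. The simulation was set to stop otherwise, or if recovery at a log2 of 2 was low. Independent genes cannot show how the list test treats correlated ones, so the runs do not bear on that. Alternatives tried were 2 other pseudocounts (0.1 and 5), no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to TPM, no variance trend, a robust prior, array weights, an estimated correlation and leaving out each library. The robust prior does not enter the list tests, so it was applied to genes only. The rotation test fry and removal of trends on transcript length and GC content were added after the data were seen.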

Results

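RNA from sorted stromal cells of the mouse large intestine was sequenced in 6 libraries, each from a different mouse. All mice were 12 weeks old and had received 1% dextran sulfate sodium (DSS), a compound given in drinking water that injures the colonic epithelium and causes colitis. Stromal cells were taken as live Podoplanin-positive cells without CD45, CD31 or EpCAM, which mark leukocytes, endothelial cells and epithelial cells. The control group held 3 mice with floxed Il10ra alleles (numbers 8, 9 and 43). The Pdgfra-cre group held 3 mice with the same alleles and a cre recombinase expressed from Pdgfra, a fibroblast gene (numbers 13, 23 and 25). Il10ra encodes the ligand-binding chain of the interleukin-10 receptor. The deposited unit was FPKM, with 11188 to 11358 genes at an FPKM of at least 1 per library. Total read numbers were not given in the sources used here, and depth was estimated roughly from the most frequent low values. These put 1 read per kilobase of transcript at 0.112 to 0.138 FPKM in the 6 libraries. Ratios of shared low values put depth at 0.885 to 1.04 times that of control library 8. Both were sought only within a range set in advance, so a large difference in depth could not have shown. The comparison asked what differed in these cells between the genotypes, and the series title names type I interferon signaling as its subject.

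The targeted gene was absent from most libraries of both groups. Il10ra (chromosome 9, 45253837 to 45269149, mm10) had an FPKM of 0.42 in control library 43 and was listed at 0 in control libraries 8 and 9 and in all 3 Pdgfra-cre libraries. An exact two-sided permutation test gave p = 1, and 0.1 is the smallest p that 3 libraries against 3 allow. By the rough depth estimate above, 1 read of this gene corresponded to about 0.0341 FPKM and 3 reads to about 0.102 FPKM. On the same estimate about 12.2 reads lay behind the value in control library 43. With 2 of 3 controls listed at 0, deletion could not be shown. The deleted exon was not given in the sources used here, and a gene-level value need not show it. Il10rb, which encodes the second receptor chain, was expressed in all libraries, with 59.5 ± 6.81 FPKM in controls and 55.8 ± 5.20 in Pdgfra-cre (SD, n = 3 each; adjusted p = 0.869). Il10 itself lay between 0 and 0.0957 FPKM.

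The genes behind the sort separated into expressed and nearly absent ones. Pdpn, which encodes Podoplanin, had 92.2 ± 12.3 FPKM in controls and 107 ± 18.3 in Pdgfra-cre (SD, n = 3 each; adjusted p = 0.718). Ptprc, which encodes CD45, lay between 0 and 1.04 FPKM, Pecam1 between 0.0741 and 0.856, and Epcam between 0 and 1.11, and none of these 3 genes was tested. The highest Ptprc and Epcam values were both in Pdgfra-cre library 23. Pdgfra had 188 ± 11 FPKM in controls and 150 ± 26.9 in Pdgfra-cre (SD, n = 3 each). Its groups did not overlap, but its log2 fold change of -0.34 ± 0.14 (SE) did not pass (adjusted p = 0.411).

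No gene passed the test between genotypes, although several abundant stromal genes differed by far more than the spread of their libraries. Cd34, a surface marker of a fibroblast subset, was 343 ± 12.1 FPKM in controls and 584 ± 16.3 in Pdgfra-cre (SD, n = 3 each; chromosome 1, 194938819 to 194961279). Apoe, which encodes a lipid carrier, was 784 ± 18.3 FPKM in controls and 350 ± 85.3 in Pdgfra-cre (chromosome 7, 19696109 to 19699188). The log2 fold changes were 0.77 ± 0.097 for Cd34 and -1.19 ± 0.16 for Apoe (SE), on the log2(FPKM + 1) scale, and the adjusted p was 0.107 for each. With higher values in Pdgfra-cre came Igfbp6 (262 to 433 FPKM), Slit3 (80.7 to 132), the glucocorticoid-responsive Fkbp5 (18 to 39.9) and Msln (0.323 to 13.7), as group means. With lower values came the gap junction gene Gja1 (223 to 100 FPKM), Svopl (13.7 to 3.17) and Rasl11a (178 to 89.7). These genes were among those with the lowest unadjusted p in each direction, out of genes with a mean FPKM of at least 5 whose groups did not overlap. Their adjusted p lay between 0.107 and 0.147. Fold changes on this scale understate differences in genes with low FPKM.

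Of 11429 genes tested with limma, 0 passed an adjusted p of 0.05, and 1253 had an unadjusted p under 0.05, of which 625 were higher and 628 lower in Pdgfra-cre. The groups did not overlap in 16.4% of the tested genes, against the 10% that chance gives for 3 against 3. The count changed when 1 library was left out. Without Pdgfra-cre library 25 it was 33 genes, of which 14 were higher and 19 lower. Those included Reg3b, Msln, Gbp4, Gbp6, Irgm1 and Tap1 with higher values and Apoe, Gja1, Nrg1, Bmp7 and Col18a1 with lower ones. Without Pdgfra-cre library 13 it was 3 (Ybx3, Sepn1 and Ppp1r14b), and without control library 43 it was 2 (Mir546 and Snora81). Mir546, a small RNA, was listed at 0 in control library 43 and lay between 34.7 and 143 FPKM in the others, and with all 6 libraries its adjusted p was 0.28. These genes were chosen after their values were seen. Library 23 stood apart from the others, with the lowest mean correlation with the other libraries (0.950, against 0.960 to 0.971 for the rest).

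**Figure D1:**
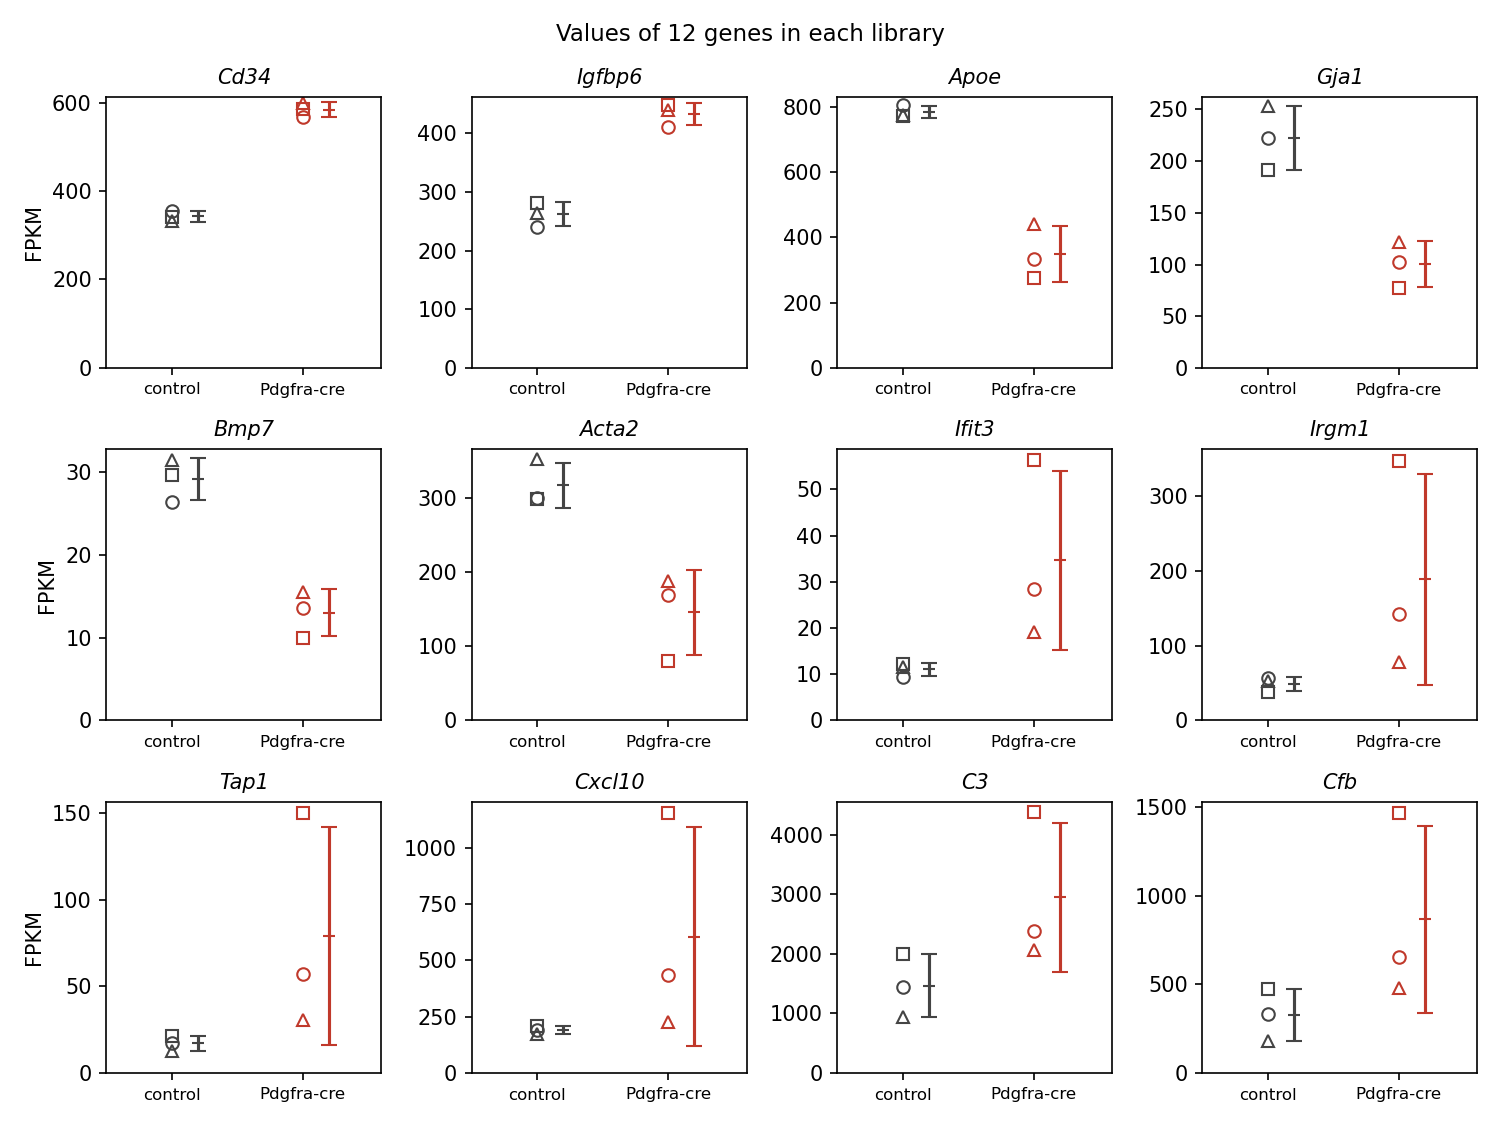
FPKM of 12 genes in each library (vertical axes, linear and starting at 0), with control libraries in grey (circle 8, square 9, triangle 43) and Pdgfra-cre libraries in red (circle 13, square 23, triangle 25). Bars beside the points give the mean and SD of the 3 libraries; Cd34 sits between 331 and 356 in controls and between 566 and 599 in Pdgfra-cre, while Ifit3 reaches 56.4 in library 23 and 19.1 in library 25.

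Type I interferon-stimulated genes, which interferon alpha and beta induce and which act against viruses, were higher in the Pdgfra-cre libraries. Of 44 tested members, 43 had a log2 fold change above 0 and the median was 0.77. Ifit3 was 11.1 ± 1.46 FPKM in controls and 34.6 ± 19.4 in Pdgfra-cre (SD, n = 3 each; chromosome 19, 34583531 to 34588731). Irf7, a transcription factor that amplifies the type I response, was 21.2 ± 5.50 and 51.9 ± 25.7 FPKM. Sp100 went from 15.6 ± 0.828 to 30.4 ± 9.93 FPKM and the 2'-5' oligoadenylate synthetase-like gene Oasl2 from 16.0 ± 2.36 to 31.7 ± 12.1. Each of these 4 had higher values in 3 of 3 Pdgfra-cre libraries than in any control. The exception in direction, chosen after its values were seen, was Ifit2 (12.8 ± 1.80 and 12.2 ± 2.60 FPKM).

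The list passed limma's camera test (adjusted p = 8.88e-18, with a preset correlation between genes of 0.01). The call was lost when the correlation was estimated from the libraries (adjusted p = 0.517 with an estimated correlation). Adjusted over all genes 0 members passed, and adjusted over the list alone 18 did, all of them higher. The groups did not overlap in 19 members, against 10% by chance. At the preset correlation the 9 other ways of dividing the 6 libraries into 3 and 3 called 4 to 16 pathway lists, against 14 for the genotypes. Those splits keep part of any genotype difference, since each side holds both genotypes in unequal number. Their counts are therefore not a rate of false calls. Calls at that setting are still weak evidence of a genotype difference, since 0 pathway lists passed with an estimated correlation. The per-library mean of the list was 3.73 ± 0.084 in controls and 4.48 ± 0.58 in Pdgfra-cre on the log2 scale (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). The 3 Pdgfra-cre libraries ranged widely, at 5.10 in library 23, 4.40 in library 13 and 3.95 in library 25, and without library 23 the median log2 fold change was 0.42.

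Genes of interferons themselves were near 0 in these sorted cells. Cells with CD45, CD31 or EpCAM had been sorted out, so interferons made by them would not be seen. Ifnb1, Ifna2, Ifna5, Ifna11, Ifne, Ifnk, Ifnl2 and Ifnl3 were listed at 0 in all 6 libraries and Ifna4 was above 0 only in Pdgfra-cre library 13 (0.477 FPKM). The receptor gene Ifnar2 was 138 ± 20.2 FPKM in controls and 152 ± 28.9 in Pdgfra-cre (SD, n = 3 each; adjusted p = 0.844). This list of interferon ligands and receptors had 4 tested members, too few for the set test, with a median log2 fold change of 0.052.

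**Figure D2:**
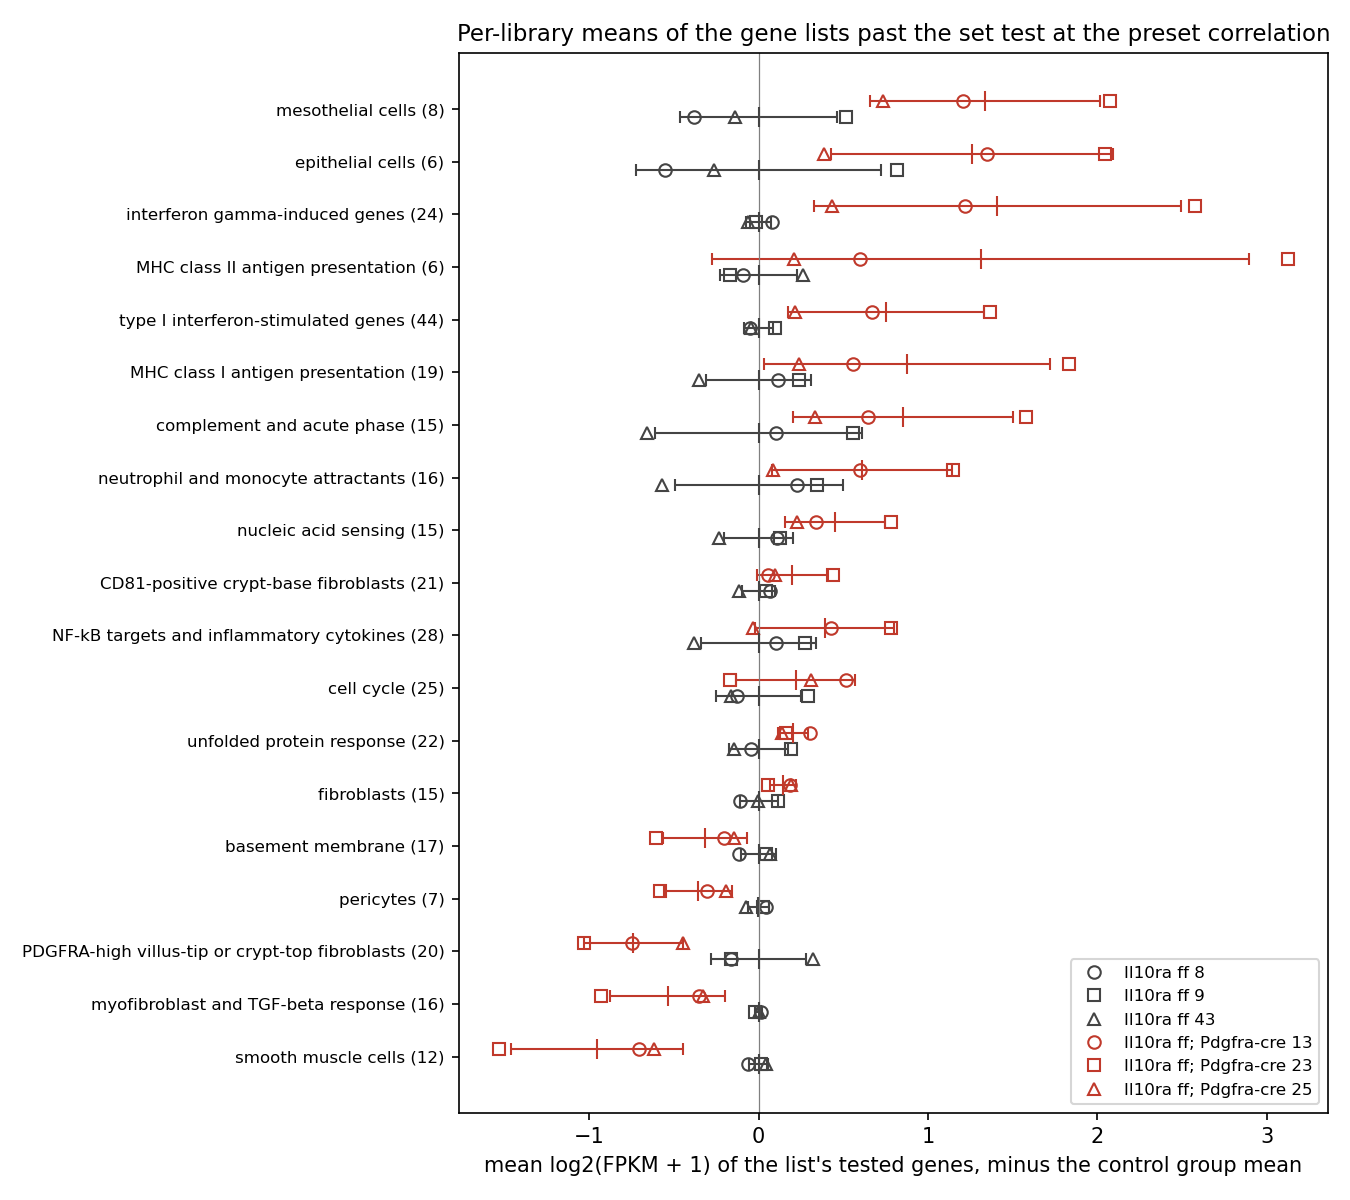
Mean log2(FPKM + 1) of the tested genes of each list, minus the control group mean (horizontal axis), for the lists with a camera adjusted p under 0.05 at the preset correlation; the number of tested genes is in brackets. Points are libraries and the ticks with bars are group means ± SD; the 3 Pdgfra-cre libraries lie above all controls for type I interferon-stimulated genes, with library 23 farthest out, and below all controls for smooth muscle cells.

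Genes induced by interferon gamma, among them the guanylate-binding proteins and immunity-related GTPases that defend cells against intracellular microbes, were higher in the Pdgfra-cre libraries. All 24 tested members had a log2 fold change above 0, with a median of 1.48. Gbp4 was 4.97 ± 1.19 FPKM in controls and 34.3 ± 28.0 in Pdgfra-cre, Gbp6 was 11.4 ± 1.55 and 50.6 ± 38.1, and Irgm1 was 48.9 ± 9.33 and 189 ± 141 (SD, n = 3 each). The groups did not overlap in 21 members, and 22 passed adjusted over the list alone, but 0 passed over all genes. The list passed camera (adjusted p = 8.88e-18, and 0.517 with an estimated correlation), and its median was 0.86 without Pdgfra-cre library 23. The list's per-library mean was highest in library 23, at 6.89 against 5.53 in library 13 and 4.74 in library 25. The mean of neutrophil markers was highest there too (5.07). Ifng was listed at 0 in all 6 libraries, from which cells with CD45 had been sorted out. Members of these gene families resemble each other closely, so reads may have been divided between them.

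Antigen presentation genes were higher as groups, but the per-library means of both lists overlapped between genotypes (exact permutation p = 0.2 for each). Of the MHC class I list, 19 of 19 tested members had a log2 fold change above 0 (median 0.76), and the groups did not overlap in 7. The peptide transporter gene Tap1 was 17.1 ± 4.43 FPKM in controls and 79.1 ± 62.8 in Pdgfra-cre, the immunoproteasome subunit gene Psmb9 was 32.0 ± 1.44 and 95.8 ± 75.4, and Tapbp was 207 ± 19.3 and 306 ± 84.3 (SD, n = 3 each). All 6 tested MHC class II members were above 0 (median 1.40). The invariant chain gene Cd74 was 108 FPKM in library 23 but 17.3 and 15.4 in libraries 13 and 25, against 6.83 to 10.8 in controls. H2-Aa was 65.8 FPKM in library 23 and 3.27 to 9.36 in the other 5, and H2-DMb1 was 20.4 and 4.81 to 7.79. Neutrophil markers and Ptprc were highest in library 23 as well: S100a8 was 94.7 FPKM there and 0 to 9.42 elsewhere, Ptprc was 1.04, and the mean of the neutrophil list was 5.07 on the log2 scale against 0.22 to 2.33. Adjusted over the list alone 0 members of either list passed. The adjusted p was 8.69e-10 for class I and 0.00102 for class II, and both calls were lost (adjusted p = 0.517 with an estimated correlation). Without library 23 the medians were 0.30 for each, and the class II median was 0.89 without a filter.

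Sensors of nucleic acids also lay higher, with 11 of 15 tested members above 0 and a median log2 fold change of 0.40. The interferon-inducible DNA sensor family genes Mnda (26.5 ± 5.12 to 59.6 ± 23.8 FPKM), Ifi204 (38.2 ± 13.7 to 76.3 ± 20.7) and Ifi205 (148 ± 58.7 to 308 ± 98.3; SD, n = 3 each) had no overlap between groups. These and Trex1, a DNA exonuclease, were the 4 members that passed adjusted over the list alone, and 0 passed over all genes. The list's adjusted p was 0.00048, and 0.517 with an estimated correlation. Its per-library mean was 4.92 in Pdgfra-cre library 23, 4.47 in library 13 and 4.36 in library 25, against 3.90 to 4.26 in controls. Without library 23 the median was 0.29 (camera adjusted p = 0.00276).

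Inflammatory genes of stromal cells were higher as groups, but the per-library means overlapped between genotypes for attractants (exact permutation p = 0.3), NF-kB targets (0.3) and complement and acute phase (0.2). All 3 means were highest in Pdgfra-cre library 23, where the neutrophil gene S100a8 was highest too (94.7 FPKM). Of the attractants of neutrophils and monocytes, 16 of 16 tested members had a log2 fold change above 0 (median 0.52). Cxcl1, a neutrophil chemokine, was 2108 ± 447 FPKM in controls and 3417 ± 943 in Pdgfra-cre, and Cxcl3 was 0.547 ± 0.379 and 2.19 ± 0.091 (SD, n = 3 each). The monocyte chemokines Ccl7 (1255 ± 410 and 2362 ± 1043 FPKM) and Ccl2 (712 ± 295 and 1367 ± 537) overlapped between groups. In the complement and acute phase list 14 of 15 members were above 0 (median 0.67). Cfb was 328 ± 145 and 867 ± 527 FPKM, C3 was 1460 ± 528 and 2944 ± 1256, and Serping1, the C1 inhibitor gene, was 2649 ± 251 and 3599 ± 614. In the NF-kB list 23 of 28 members were above 0 (median 0.27), with Icam1 at 329 ± 35.5 and 452 ± 90.1 FPKM.

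Adjusted over all genes 0 members of these 3 lists passed, and adjusted over the list alone only Cxcl3 did. Cxcl3 was at 0.130 to 0.870 FPKM in controls and met the filter through the Pdgfra-cre libraries alone, which favors higher values there. Its log2 fold change ran from 0.38 to 2.06 under the alternatives that kept all libraries. The camera adjusted p was 4.41e-05 for the attractants, 7.37e-06 for complement and acute phase and 0.00168 for NF-kB targets, and each was 0.517 with an estimated correlation. Without Pdgfra-cre library 23 the medians were 0.24, 0.42 and 0.13, and the NF-kB call was lost (adjusted p = 0.167). It was lost too without control library 43 (median 0.18, adjusted p = 0.106), while without Pdgfra-cre library 25 its median was 0.41. The NF-kB median was 0.13 with array weights and 0.18 after rescaling to TPM, and the list shares 4 genes with the attractants and 2 with complement and acute phase. The attractant median was 0.34 without control library 43 and 0.90 without Pdgfra-cre library 25, and that of complement and acute phase was 1.26 without control library 9.

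Fibroblasts with high PDGFRA, which lie under the surface epithelium and secrete bone morphogenetic proteins, had lower marker levels in the Pdgfra-cre libraries. All 20 tested members had a log2 fold change below 0, with a median of -0.64. Nrg1, an epidermal growth factor family ligand, was 21.2 ± 7.39 FPKM in controls and 3.34 ± 1.88 in Pdgfra-cre. Bmp7 was 29.1 ± 2.54 and 13 ± 2.85 FPKM (chromosome 2, 172868012 to 172940321), and Bmp5 was 72.6 ± 20.7 and 27.9 ± 8.23 (SD, n = 3 each). The groups did not overlap in 11 members, 9 passed adjusted over the list alone and 0 over all genes. The list's adjusted p was 3.6e-12 (adjusted p = 0.517 with an estimated correlation). Its per-library mean was below that of every control in 3 of 3 Pdgfra-cre libraries. The mean was lowest in library 23, at 3.67 against 3.95 in library 13 and 4.25 in library 25. Without library 23 the median was -0.47.

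The myofibroblast and TGF-beta response list was lower as a group, with 11 of 16 tested members below 0, 5 above and a median log2 fold change of -0.65. Smooth muscle markers, which share Acta2, Actg2 and Cnn1 with it, were lower too (12 of 12 below 0, median -1.04, adjusted p = 7.29e-11; adjusted p = 0.179 with an estimated correlation). Tpm1 was 371 ± 22 FPKM in controls and 239 ± 30.6 in Pdgfra-cre, Cnn1 was 43.9 ± 8.11 and 18.9 ± 7.25, and Acta2, which encodes smooth muscle actin, was 317 ± 30.8 and 146 ± 57.3 (SD, n = 3 each). Adjusted over the list alone 9 members passed, all lower, and 0 passed over all genes. The TGF-beta feedback gene Smad7 (2.66 ± 0.239 and 3.76 ± 0.126 FPKM), Tgfb2 and Tgfb3, chosen after their values were seen, were not among them. The myofibroblast list's adjusted p was 5.71e-05 (adjusted p = 0.517 with an estimated correlation). Basement membrane genes had a median of -0.15 and an adjusted p of 0.0073 (0.517 with an estimated correlation). Col18a1 (198 ± 16.7 and 91.2 ± 40.1 FPKM), which passed adjusted over the list alone, Lama5 (2.09 ± 0.812 and 0.556 ± 0.211) and Lama1 (5.86 ± 1.26 and 3.27 ± 0.802) were its lowest-p members. That call was lost without Pdgfra-cre library 23 (median -0.088, adjusted p = 0.226), under a stricter filter (adjusted p = 0.0896) and with array weights (adjusted p = 0.0931). Its median was -0.087 without a filter, -0.23 under quantile normalization and -0.25 after rescaling to TPM.

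Crypt-base fibroblasts with CD81, which supply WNT agonists to stem cells, had 14 of 21 tested markers above 0 and a median of 0.30, with per-library means that overlapped between genotypes (exact permutation p = 0.2). Cd81 was 322 ± 42.5 FPKM in controls and 452 ± 54.3 in Pdgfra-cre, and Has1, a hyaluronan synthase gene, was 841 ± 61.8 and 1130 ± 128 (SD, n = 3 each). Adjusted over the list alone 9 passed: Cd34, Cd81, Has1, Pi16, C3, Ly6c1 and Ly6a were higher, and the growth factor genes Wnt2 and Fgf10 were lower. None passed over all genes. The list's adjusted p was 0.0134 (0.517 with an estimated correlation). It was lost without control library 43 (median 0.19, adjusted p = 0.0897), without Pdgfra-cre library 23 (median 0.20, adjusted p = 0.123) and with array weights (adjusted p = 0.0675), and its median was 0.19 with a pseudocount of 5.

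**Figure D3:**
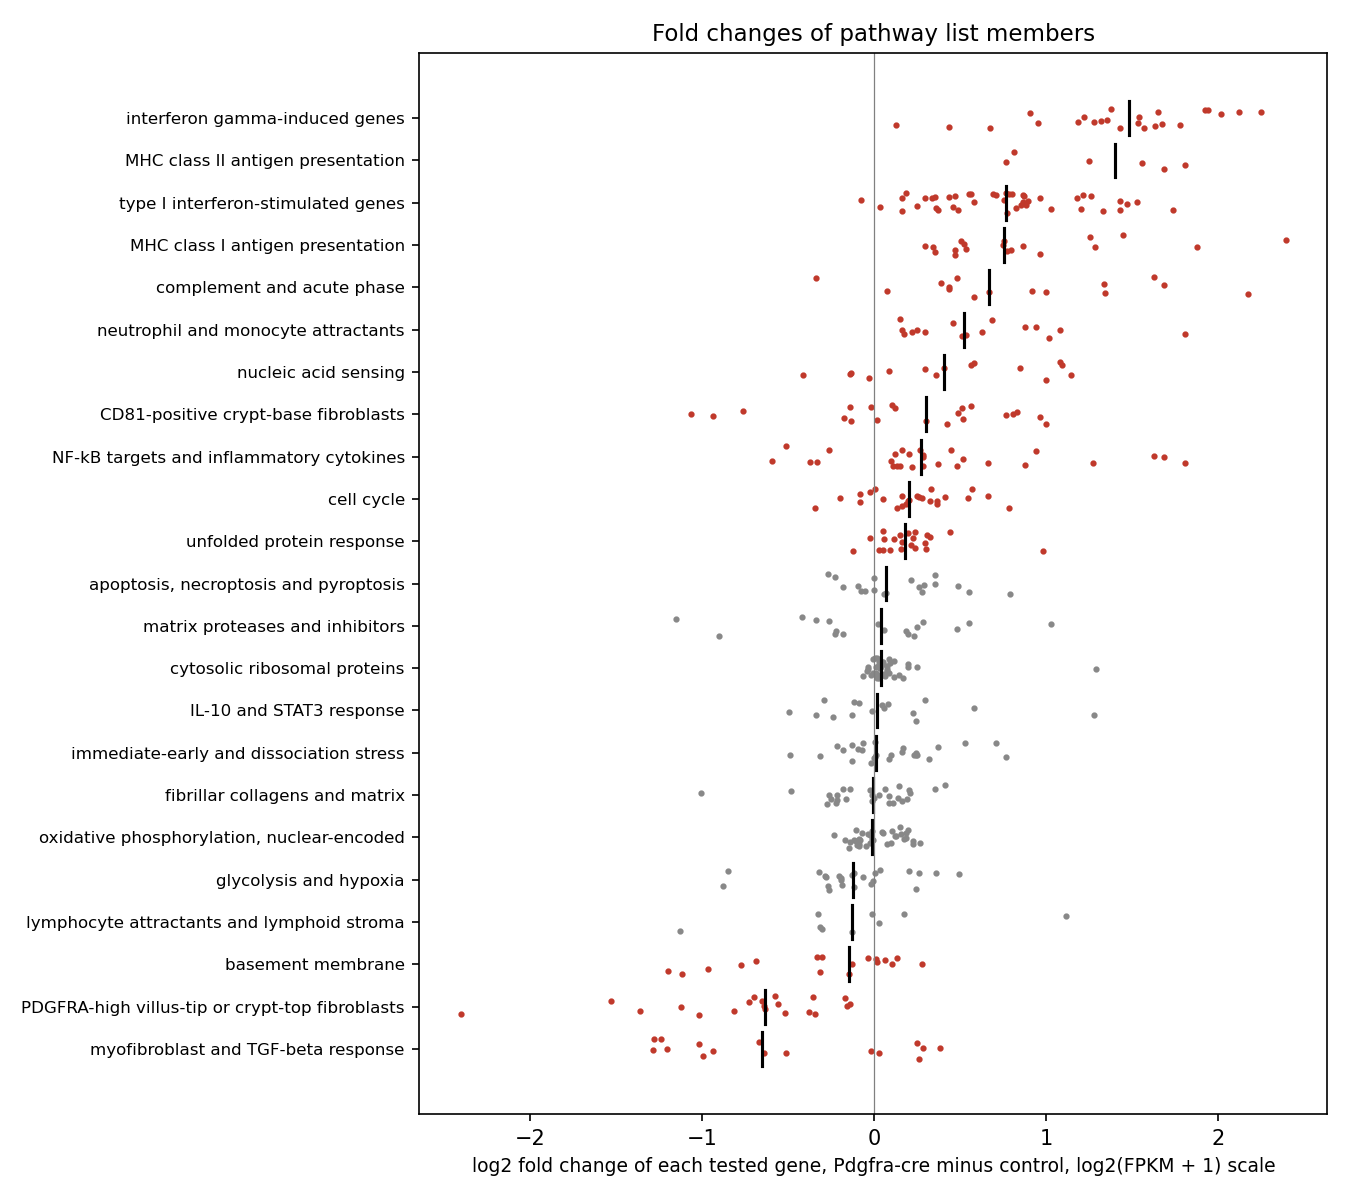
Log2 fold change of each tested gene (horizontal axis, Pdgfra-cre minus control on the log2(FPKM + 1) scale) for the 23 pathway lists with at least 5 tested genes. Each dot is a gene, black lines are list medians, and red marks the 14 lists past an adjusted p of 0.05 at the preset correlation; medians run from -0.65 for myofibroblast and TGF-beta response to 1.48 for interferon gamma-induced genes.

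Small shifts passed in 2 further lists, in which the per-library means overlapped between genotypes (exact permutation p = 0.3 for the unfolded protein response and 0.5 for the cell cycle, whose lowest mean was in Pdgfra-cre library 23). Unfolded protein response genes had a median of 0.18 with 20 of 22 members above 0, led by Asns (9.65 ± 5.40 and 18.2 ± 3.69 FPKM), Creld2 (178 ± 45.6 and 237 ± 16.4) and Pdia6 (483 ± 89.9 and 588 ± 17.9; SD, n = 3 each). The adjusted p was 0.000968 (0.517 with an estimated correlation), and the median was 0.073 under quantile normalization and 0.081 after rescaling to TPM. Cell cycle genes had a median of 0.20 and an adjusted p of 0.0135 (0.539 with an estimated correlation), with Ccne1 (9.36 ± 1.85 and 17.2 ± 5.12 FPKM), Mcm7 (6.25 ± 1.37 and 10.7 ± 3.23) and Pcna (91.7 ± 6.84 and 104 ± 10) as lowest-p members. The cell cycle call was lost without control library 8 (median 0.20, adjusted p = 0.095) or 43 (0.099, adjusted p = 0.115) and without Pdgfra-cre library 13 (0.11, adjusted p = 0.422) or 25 (0.22, adjusted p = 0.0712). Its median was 0.35 without control library 9, 0.32 without Pdgfra-cre library 23, 0.30 with a pseudocount of 0.1, 0.12 with a pseudocount of 5 and 0.32 with array weights. Adjusted over the list alone 0 members of either list passed.

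The remaining 9 tested pathway lists did not pass at the preset correlation. Genes of the IL-10 and STAT3 response had a median of 0.016 (adjusted p = 0.888), with Junb at 908 ± 133 FPKM in controls and 823 ± 47.3 in Pdgfra-cre (SD, n = 3 each). Fibrillar collagens and matrix had a median of -0.005 (adjusted p = 0.861), with Dcn at 8841 ± 274 and 10240 ± 882 FPKM. Matrix proteases and inhibitors had a median of 0.039 with a mean of -0.024 (adjusted p = 0.861), with Mmp2 at 956 ± 85.5 and 763 ± 144 FPKM; adjusted over the list alone Mmp10 was lower and Mmp19 higher. Lymphocyte attractants and lymphoid stroma had a median of -0.13 (adjusted p = 0.193), with Cxcl12 at 1282 ± 54.9 and 1047 ± 298 FPKM, and the B cell chemokine gene Cxcl13 (693 ± 228 and 321 ± 118) was lower adjusted over the list alone. That list passed without Pdgfra-cre library 23 (median -0.45, adjusted p = 0.00224) and with array weights (-0.23, adjusted p = 0.0243). Mmp10, Mmp19 and Cxcl13 were chosen after their values were seen.

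Glycolysis and hypoxia genes had a median of -0.12 (adjusted p = 0.0692), with Ldha at 791 ± 104 FPKM in controls and 682 ± 30.8 in Pdgfra-cre (SD, n = 3 each). That list passed under quantile normalization (adjusted p = 0.0142), after rescaling to TPM (0.0197), without control library 43 (0.0125) and after removal of length and GC trends (0.0452). Oxidative phosphorylation genes had a median of -0.011 and a mean of 0.019 (adjusted p = 0.861), with Atp5b at 416 ± 8.03 and 414 ± 4.26 FPKM. Cytosolic ribosomal protein genes had a median of 0.037 (adjusted p = 0.112), with Rpl13 at 1063 ± 85.6 and 1116 ± 18.7, and the median turned negative under quantile normalization (-0.033), TPM rescaling (-0.061) and without control library 43 (-0.036). That list passed without control library 9 (median 0.12, adjusted p = 5.41e-05) and without Pdgfra-cre library 25 (0.097, adjusted p = 0.0041). Immediate-early and dissociation stress genes had a median of 0.011 (adjusted p = 0.134), but their per-library means were higher in 3 of 3 Pdgfra-cre libraries than in any control, by 0.091 ± 0.045 (SE; exact permutation p = 0.1, the smallest possible), so a difference in sample handling was not excluded. Fos was at 3286 ± 274 and 3136 ± 203 FPKM, and Atf3 (683 ± 28.7 and 985 ± 54.5), chosen after its values were seen, was higher adjusted over the list alone. Genes of apoptosis, necroptosis and pyroptosis had a median of 0.071 (adjusted p = 0.134), with Mcl1 at 99.7 ± 33.2 and 141 ± 13.5, and passed without Pdgfra-cre library 25 (median 0.17, adjusted p = 0.04). The list of mitochondrial-encoded transcripts had 0 measured members.

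Among markers of other cell types, those of smooth muscle were lower in the Pdgfra-cre libraries. Those of mesothelium were higher, as were 5 of the 6 epithelial markers that could be tested. All 12 smooth muscle markers had a log2 fold change below 0 (median -1.04; adjusted p = 7.29e-11, and 0.179 with an estimated correlation), 11 had no overlap between groups and 10 passed adjusted over the list alone. It shares Acta2, Actg2 and Cnn1 with the myofibroblast list. Mesothelial markers had a median of 1.52 (adjusted p = 2.5e-05, and 0.179 with an estimated correlation), with Msln, Upk3b and Upk1b passing adjusted over the list alone. The most abundant mesothelial marker, Nkain4, was 14.4 ± 5.83 FPKM in controls and 23.2 ± 3.96 in Pdgfra-cre (SD, n = 3 each). The 6 tested epithelial markers, of 24 measured, had a median of 1.52 (adjusted p = 0.00408, and 0.311 with an estimated correlation) and low levels. The filter can admit a gene through the Pdgfra-cre libraries alone, which favors higher values there. Without a filter the epithelial median was 0.21 (camera adjusted p = 0.00602). That list shares 2 genes with the mesothelial list, so their calls are not separate, and its per-library means overlapped between genotypes (exact permutation p = 0.2). Lgals4 was 5.71 ± 2.24 and 5.10 ± 2.03 FPKM, and the antimicrobial lectin gene Reg3b, which passed adjusted over the list alone, was 0.0627 ± 0.109 and 8.98 ± 6.37. Pericyte markers had a median of -0.31 (adjusted p = 0.0103, and 0.179 with an estimated correlation), with Pdgfrb at 41.6 ± 4.56 and 33.5 ± 5.02 FPKM, and Kcnj8 passing adjusted over the list alone. General fibroblast markers had a median of 0.14 (adjusted p = 0.0231, and 0.179 with an estimated correlation), and Cd34, Mfap5 and Dpt passed adjusted over the list alone, while the per-library means overlapped (exact permutation p = 0.2). Apart from the most abundant marker of each list, these markers were named after their values were seen.

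Over all genes 0 of these markers passed. Without Pdgfra-cre library 23 the medians were 0.99 for mesothelial, 0.94 for epithelial and -0.19 for pericyte markers, and the pericyte median was -0.20 with array weights. The fibroblast call was lost without control library 8 (median 0.033, adjusted p = 0.182) and without Pdgfra-cre library 13 (0.14, adjusted p = 0.0693) or 25 (0.16, adjusted p = 0.121). It was also lost under quantile normalization (0.0037, adjusted p = 0.525), without a filter (adjusted p = 0.0645) and without a variance trend (adjusted p = 0.061). The fibroblast median was 0.28 without control library 9, 0.091 without control library 43 and 0.045 after rescaling to TPM. The mesothelial median was 0.71, and the epithelial one 0.68, with a pseudocount of 5. The epithelial median was 2.41 with a pseudocount of 0.1 and 0.21 without a filter.

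The other tested cell type lists did not pass. Markers of monocytes, macrophages and dendritic cells had a median of 0.17 (adjusted p = 0.284), with Lyz2 at 14.8 ± 4.91 FPKM in controls and 17.9 ± 9.94 in Pdgfra-cre (SD, n = 3 each). That list passed without Pdgfra-cre library 25 (median 0.54, adjusted p = 0.0206). Blood endothelial markers had a median of 0.0057 and a mean of -0.0079 (adjusted p = 0.897), with Tek at 31.6 ± 4.03 and 37.7 ± 4.79 FPKM, and Esam was lower adjusted over the list alone. Markers of interstitial cells of Cajal had a median of -0.11 and a mean of 0.047 (adjusted p = 0.943), with Elovl6 at 6.71 ± 1.73 and 5.83 ± 0.408 FPKM.

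Lists with fewer than 5 tested markers were not given a set test. Neutrophil markers were concentrated in Pdgfra-cre library 23, where S100a8 was 94.7 FPKM and S100a9 63.9. S100a8 was 9.42 and 6.89 FPKM in Pdgfra-cre libraries 13 and 25 and 0 to 6.84 in controls. The most abundant markers of the other lists showed smaller differences. Group means in controls and Pdgfra-cre were 110 and 128 FPKM for Fgl2 (lymphatic endothelium), 2.08 and 0.753 for Cd28 (T and NK cells), 2.81 and 4.86 for Jchain (B and plasma cells), 4.20 and 5.45 for Kit (mast cells), 12.2 and 7.16 for Stmn2 (enteric neurons) and 71.8 and 73.0 for Hba-a1 (erythroid cells). None of these passed over all genes, and their adjusted p lay between 0.466 and 0.988. The most abundant marker need not stand for its list. Of 3 tested enteric neuron markers 2 were above 0 (median 0.75), and Stmn2 was the exception. Of 4 tested lymphatic endothelial markers 2 were above 0 and 2 below (median -0.039).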

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

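The count of 0 genes held under all 11 alternatives that kept 6 libraries, with a lowest adjusted p of 0.0643 to 0.373. Leaving out 1 library gave 0 to 33 genes: 2 without control library 43, 3 without Pdgfra-cre library 13, 33 without Pdgfra-cre library 25 and 0 otherwise. Rescaling to TPM shifted the median log2 fold change by -0.091, so that 420 genes were higher and 874 lower at an unadjusted p under 0.05, against 625 and 628. The median of the type I interferon list stayed between 0.52 (pseudocount 5) and 0.81 (pseudocount 0.1), and between 0.42 and 1.05 when 1 library was left out. It was 0.77 with an estimated correlation (adjusted p = 0.517) and 0.77 with fry (adjusted p = 0.335), and neither passed. The number of pathway lists called, 14, became 0 with an estimated correlation and 0 with fry, was 12 to 15 under the other settings, and was 12 to 15 when 1 library was left out. The number of cell type lists called, 5, became 0 with an estimated correlation (lowest adjusted p 0.179), 0 with fry (0.101) and 2 with the filter of 5 FPKM, where only 2 lists were large enough to test. It was 4 to 5 when 1 library was left out. Both set test alternatives allow for correlated genes, which the preset value of 0.01 nearly ignores. Fry also tests a list against no change, while camera tests it against the other genes, so the fry counts differ in more than correlation. The adjusted p of 0.517 shared by many pathway lists hides a ranking. Unadjusted camera p with an estimated correlation was 0.0546 for PDGFRA-high fibroblasts, 0.103 for interferon gamma-induced genes and 0.35 for NF-kB targets. The Il10ra difference was -0.29 to -0.17 under the 3 scalings and -0.25 to 0 when 1 library was left out, with no call. The 2 filters do not enter its value, so they were no check on it. No named gene was called with all 6 libraries, so no gene could lose a call or reverse a called direction. Of 1335 values for 79 named genes, 1306 stayed uncalled with the same sign and 17 changed in sign. The other 12 gained a call, all without Pdgfra-cre library 25. Of 533 values for the other 30 lists, 435 kept their sign and stayed called or uncalled, 54 lost the call, 10 gained a call and 34 changed in sign. No called list reversed its direction. For the changes that came with single libraries, the cause was not tested. Fry and the removal of length and GC trends were added after the data were seen.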

Other observations

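The splits of the libraries and the list medians with single libraries left out were planned. The other tests and the genes Saa3, Ciita and Adamdec1 were chosen after the gene-level results were seen.

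Interferon-responsive genes were higher in the Pdgfra-cre libraries, and Saa3, an acute phase gene, was also highest in library 23, although its groups overlapped (2022, 3036 and 654 FPKM in 13, 23 and 25, against 202 to 1022 in controls). The difference might rest on library 23, and without it the mean log2 difference of the type I list was 0.44 ± 0.23 (SE), 1.91 SE from 0, which leaves this open. Transcript length and GC content do not account for it, since the median was 0.76 after both trends were removed and 0.77 before. A larger share of CD34-positive fibroblasts remains possible, since the interferon gamma-induced list moved by 0.64 ± 0.63 (SE) more than Cd34. Cd34 was nearly even in libraries 13, 23 and 25 (566, 587 and 599 FPKM), while the list's mean log2 values were 5.53, 6.89 and 4.74. The spread of the list among the Pdgfra-cre libraries therefore did not follow Cd34. The 10 splits of the libraries are too few for a share under 0.05. The type I median was 0.77 (highest other 0.66, with 1 of 10 as large). Pathway lists called were 14 (highest other 16, with 5 of 10) and cell type lists 5 (highest other 4, with 1 of 10). Genes called were 0 (highest other 1), a value that 10 of 10 splits reach by construction. Genes with an unadjusted limma p under 0.05 numbered 1253 for the genotypes and 312 to 767 in the other splits. That count was not among those planned for the splits. The other splits keep part of any genotype difference, so they do not show what its absence would give.

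Interferon gamma-induced genes moved more than type I genes. Ciita, the activator of MHC class II genes, was at 0.142 to 0.297 FPKM in the Pdgfra-cre libraries and 0 to 0.0238 in controls. Ciita belongs to both the interferon gamma-induced and the MHC class II list. It lay below the filter and was not tested, and values this low rest on few reads. The difference between the list means was larger by 0.66 ± 0.30 (SE) in Pdgfra-cre, at 0.790 to 1.79 against 0.463 to 0.704 in controls (exact permutation p = 0.1), and without library 23 the interferon gamma-induced median was 0.86 and the type I median 0.42. Whether a type I or a type II response produced this was not tested. Type I interferon also induces many of these genes, so the ligand may be either or both. Ifng and Ifnb1 were listed at 0 in all libraries. Cells with CD45 were sorted out, so these values do not bear on ligands made by such cells. No proteins and no mice without DSS were analysed here.

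Markers of PDGFRA-high fibroblasts were lower in the Pdgfra-cre libraries. Adamdec1, a metalloprotease gene of lamina propria fibroblasts, was at 982 to 1201 FPKM in the Pdgfra-cre libraries and 1352 to 3274 in controls. It is not in the PDGFRA-high list but in the CD81-positive crypt-base list, and it went against that list's direction (median 0.30). Fewer smooth muscle cells in the sort may explain the smooth muscle list and the 3 genes it shares with the myofibroblast list, although the sort took only Podoplanin-positive cells, and whether they also bear on the PDGFRA-high list, which shares no gene with it, was not tested. Transcript length and GC content do not account for the PDGFRA-high list (median -0.65 after removal of both trends, -0.64 before). A loss of these cells and lower expression within them would look alike in sorted bulk RNA, and a group with cre but without floxed alleles was not analysed here, so an effect of the cre allele remains possible.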
